A study of Mus musculus with 2 samples.

How the data were processed

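Single-cell RNA sequencing of transcript 3′ ends was done on CD45-selected cells from 2 groups of tumours, 1 library per group, per the labels' protocols. The authors deposited 1 pooled matrix of raw UMI counts over 31053 genes and 12514 barcodes, made with Cell Ranger against mm10, per the submitters' processing notes; the software version is 3.1.0, per the file headers. The aligner settings, the gene annotation, the rule for calling cells and whether reads were subsampled when the libraries were joined are not given in the sources used here. The deposited counts are whole numbers of UMIs with no normalization. The strand used in counting is not given in the sources used here, so antisense genes such as Tsix are uncertain. Each barcode ends in a library number, 8 barcode sequences occur in both libraries, and no source maps the numbers to the groups. The libraries were therefore kept as unlabelled library 1 and library 2.

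Cells needed at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs. This left out 79 barcodes of library 1 and 95 of library 2 for mitochondrial UMIs and 1 of library 2 for its genes. The lowest totals, 4166 and 4810 UMIs, lie far above the UMI minimum, so a stricter limit had already been applied to the matrix. Doublets were scored per library with Scrublet at an expected rate of 0.06. Its automatic threshold marked 0.0% of barcodes, so by the rule set beforehand the 5% of barcodes with the highest scores, 266 and 360, were removed. The 4977 and 6740 cells kept held 52137468 and 133960782 UMIs. Mitochondrial UMIs had a median of 4.00% in library 1 and 2.10% in library 2, and Gm42418, which overlaps ribosomal RNA, took 25407 and 7497 CPM.

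Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen without mitochondrial, ribosomal, sex-check and receptor variable genes. They were reduced to 30 principal components, and cells were joined to 15 nearest neighbours and clustered with Leiden at resolution 1 without batch integration. The 24 clusters were named from 24 marker lists (all 170 marker genes were found) and are called X-like. A name needed at least 3 raised markers. The score limits, and the rule that sets clusters with under 100 CPM of Ptprc apart as Ptprc-low, were set after the data were examined. Clusters with the markers of more than 1 lineage were called mixed. Clusters with scores or raised markers under the limits, or with more markers of another list than of their own among their 10 leading genes, were left unnamed. Cluster 8, led by histone genes, has no marker of any list among its leading genes and was named T cell-like from 7 raised markers. Naive-type T cell-like clusters are those with a high score for the naive and memory list; T cell-like clusters with none of the narrower names are called other T cell-like.

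Of 301 genes in 25 function lists fixed before the data were examined, 300 were found, and 71 gene IDs carry a symbol that another ID shares. Gene levels are UMIs summed over a class as CPM with exact Poisson intervals. The leading class of a gene was found within each library among the named CD45-positive classes and cluster 4, where these had at least 200000 UMIs in both libraries, and for genes of at least 10 CPM; these limits were set after the data were examined. Differences between libraries are log2 ratios of CPM with exact conditional binomial intervals, in the 3 largest classes with at least 100 cells in each library, and a zero was set to a floor of 3 counts. A list's median was set against 10000 random lists of the same size matched on mean expression, for lists with at least 5 measured genes. Shares of cells have exact Clopper-Pearson intervals. Intervals are at the 95% level and cover counting error only. No test was made and no p-value is given, since each group has 1 library and cells are not replicates.

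Genes are named by a rule set before the data were examined. Members of a fixed function list may be named with their values. In each of the 3 classes, so may the 10 genes with the highest and the 10 with the lowest ratio among those with at least 100 UMIs in the class, at least 50 CPM in 1 library, a ratio of at least 2-fold and an interval that excludes 1.5-fold, leaving out ribosomal, mitochondrial, sex-check, immunoglobulin and receptor variable genes. Counts of list members past the 2-fold limit use the same ratio and interval conditions without the CPM minimum. The comparison covered 2983 genes in macrophage-like, 2636 in other T cell-like and 2514 in NK cell-like cells.

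Free RNA in each class and library was estimated from markers that the class should lack. Where the estimate for a gene exceeded its level, the estimate was too high for that gene. A gene was said to stay at the level of free RNA when its ratio fell under 2-fold after subtraction, or when free RNA made up at least 0.5 of its level in the higher library. The second condition was added after the ratios had been seen. It removed none of the 10 genes named for library 1 in any class, and left 7, 5 and 6 of the 10 genes named for library 2 in macrophage-like, other T cell-like and NK cell-like cells. Coordinates are from GENCODE for GRCm38, the assembly that mm10 names.

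The ratio and naming step was tested on simulated data for the macrophage-like comparison. Among 2773 genes it named 20 of 50 genes changed 2-fold, all 50 of those changed 3-fold, 4-fold and 8-fold, and none of 2573 unchanged genes. Of 200 unchanged lists, 6 lay outside the central 95% of random lists, and a raised list of 26 genes lay at percentile 100.

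Alternatives fixed before the data were examined covered the mitochondrial limit, the UMI minimum, doublets, the clustering, the weighting of cells and clusters, free RNA in gene levels, the scaling of counts (median-of-ratios and TMM), the count minimum and the thinning of cells for the cycling share. Added afterwards were subtraction of free RNA from ratios, counting cluster 4 with the macrophage-like cells, keeping only cells of at least 10000 UMIs, and leaving Ptprc-low, mixed and unnamed clusters out of the total. A list median counted as moved when it shifted by more than 0.25 of the width of its random range. Mir21a was not analysed here. Software was Python 3.11.15 with scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors.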

Results

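Immune cells from subcutaneous tumours of MTC-Q1, a mouse oral cancer line, were profiled by droplet-based single-cell RNA sequencing of transcript 3′ ends. The labels name 2 groups with 1 library each: tumours grown from unmodified MTC-Q1 cells (WT) and tumours grown from MTC-Q1 cells in which miR-21 had been knocked out. miR-21 is a microRNA that lowers the output of the mRNAs it binds, and cisplatin is a drug that crosslinks DNA. Mice of the C57BL/6 strain carried the tumours for 2 weeks, were given cisplatin at 5 mg/kg, and gave up their tumours 72 hours later. Dead cells were removed and CD45-positive cells, that is, leukocytes, were selected with beads. The design asks how leukocytes in cisplatin-treated tumours differ with the miR-21 status of the tumour cells. The deposited count matrix pools both libraries and marks each barcode with a library number. No source used here ties that number to a group, so the libraries are called library 1 and library 2, and no difference between them is given a direction between WT and knockout. Library 1 held 5320 barcodes with 57488236 unique molecular identifiers (UMIs), a median of 7169 per barcode, and library 2 held 7194 barcodes with 149734240 UMIs, a median of 15247.5. After filtering, 4977 and 6740 cells remained. Neither group has a replicate, so no difference was tested, and every interval below is a 95% interval that covers counting error only.

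Leukocyte composition differed widely between the libraries. Library 1 was mostly lymphoid: naive-type T cell-like cells made up 54.4% of its cells (exact binomial interval 52.97 to 55.8%) against 0.237% in library 2 (0.136 to 0.385%), and B cell-like cells made up 8.82% (8.05 to 9.64%) against 0.0445% (0.00918 to 0.130%). Library 2 had larger shares of myeloid and innate cells. These are shares of all cells, so the many naive-type T cell-like and B cell-like cells of library 1 lower its other shares. Of 4977 cells in library 1, 2706 were naive-type T cell-like and 439 were B cell-like, against 16 and 3 of 6740 in library 2. No setting left those classes out of the total, and the order of the libraries among the remaining cells was not computed. The order for other T cell-like (300 and 1137 cells), gamma-delta T cell-like (28 and 60) and pDC-like cells (21 and 41) may thus rest on that total. Macrophage-like cells made up 23.5% of library 2 (22.5 to 24.5%) and 2.27% of library 1 (1.87 to 2.72%), but 15.8% and 0.904% at Leiden resolution 2.0 and 33.0% and 8.98% at resolution 0.5, so their share rests on the clustering far more than on counting error. NK cell-like cells made up 16.9% (15.997 to 17.8%) and 3.21% (2.74 to 3.74%), and monocyte-like cells 9.33% (8.65 to 10.1%) and 2.17% (1.78 to 2.61%). The monocyte-like share was 19.05% and 5.53% with 4000 variable genes, and its order turned when only cells of at least 10000 UMIs were kept (1.97% and 3.81%). The remaining T cells, here called other T cell-like, form a mixed class whose larger cluster is led by genes that include the gamma-delta receptor genes Trdc and Tcrg-C2 and Klra receptors. They made up 6.03% of library 1 (5.38 to 6.73%) and 16.9% of library 2 (15.98 to 17.8%).

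Among T cells alone, the naive-type made up 82.1% of library 1 (80.8 to 83.4%) and 1.24% of library 2 (0.710 to 2.00%), and the other T cell-like cells 9.10% and 88.1%. Regulatory T cell-like cells, which restrain immune responses, made up 5.24% of all cells in library 1 and 1.16% in library 2, but 7.92% and 6.04% of the T cells. Their share of library 2 was 1.90% at Leiden resolution 0.5, 1.74% with 15 principal components and 0.545% among cells of at least 10000 UMIs. Gamma-delta T cell-like cells made up 0.563% and 0.890% of all cells, an order that turned among cells of at least 10000 UMIs (0.592% and 0.273%). Conventional and migratory dendritic cells, which present antigen to T cells, took smaller shares of all cells in library 1. The cDC2-like class took 0.844% and 5.53%, the cDC1-like class 0.221% and 1.71%, and the migratory DC-like class 0.382% and 1.56%. The cDC2-like share of library 2 was 9.32% at Leiden resolution 0.5, and among cells of at least 10000 UMIs the class took 2.43% and 4.49%. The pDC-like class took 0.422% (0.261 to 0.644%) and 0.608% (0.437 to 0.824%), and its order turned among cells of at least 10000 UMIs (1.18% and 0.147%). The gamma-delta T cell-like and cDC1-like classes were not found as clusters of their own with 15 principal components or at Leiden resolution 0.5. No cluster met the criteria for neutrophils, and the neutrophil marker list summed to 47.4 CPM (UMIs scaled to the total of the library or class, the unit of all levels below) in library 1 and 134 CPM in library 2. In library 2 the list stood at 3860 CPM in cluster 24, whose leading genes include the listed marker Mmp9, and at 641 CPM in cDC2-like cells. The higher sum of library 2 is thus not read as more neutrophils.

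**Figure D1:**
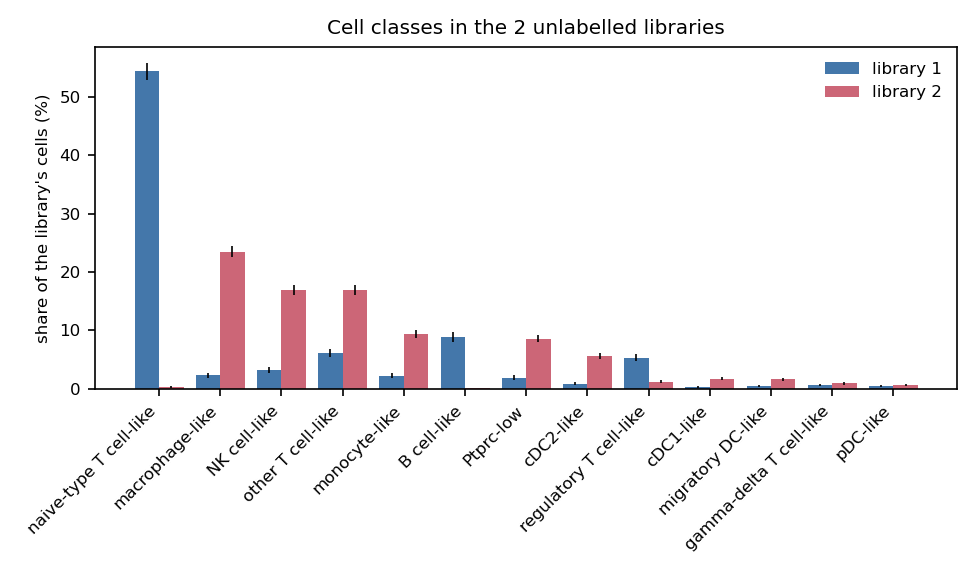
Share of each library's cells (percent, vertical axis) in each named class, with exact binomial 95% intervals as error bars; blue bars are library 1 and red bars are library 2. Naive-type T cell-like cells take 54.4% of library 1, and macrophage-like cells take 23.5% of library 2.

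CD45 bead selection, dead-cell removal and the lowest UMI total per barcode (4166 in library 1 and 4810 in library 2) can all set these shares, and a cluster found mostly in 1 library may be that library rather than a cell type. Clusters low in Ptprc, the gene for CD45, took 1.87% and 8.56% of cells, clusters with markers of more than 1 lineage (clusters 12 and 17) 6.89% and 1.94%, and unnamed clusters (4, 21 and 24) 6.69% and 11.2%, of which cluster 4 alone took 6.67% and 9.63%.

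Gene levels were set side by side within each library across the named CD45-positive classes and cluster 4, where these had at least 200000 UMIs in both libraries. Leading, highest and peak below hold within that set, which leaves out the Ptprc-low, mixed and other unnamed clusters and the B cell-like and naive-type T cell-like classes. Of 273 listed genes measured at 10 CPM or more, 171 had the same leading class in both libraries, and this held for over 0.5 of the genes in 18 of 24 lists. Lists where it mostly failed include MHC class I presentation (3 of 10), naive and memory T cells (3 of 8), dissociation stress (7 of 16) and G2 and M phase (7 of 27). A lead describes the cluster itself where the gene is among the genes that lead it. The p53 pathway answers DNA damage by halting division or starting cell death, and 18 of its 19 listed targets were measured at 10 CPM or more. For 12 of them the same class led in both libraries, and for 7 that class was the macrophage-like one. Cdkn1a, an inhibitor of cyclin-dependent kinases, stood there at 955 CPM in library 1 (exact Poisson interval 915 to 996) and 1063 CPM in library 2 (1052 to 1075), with the monocyte-like class next at 861 and 1042 CPM. Bax, which permeabilises mitochondria in apoptosis, stood at 326 CPM (303 to 351) and 444 CPM (437 to 452). Phlda3, an inhibitor of Akt signalling, stood at 84.7 CPM (73.2 to 97.6) and 93.6 CPM (90.2 to 97.1), against 46.7 and 29.0 CPM in cluster 4, the next highest.

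The type I interferon list had its peak in monocyte-like cells. For 17 of its 20 genes the same class led in both libraries, and for 16 it was that one. Isg15, a ubiquitin-like protein induced by interferon, stood at 2181 CPM (2098 to 2267) in library 1 and 2486 CPM (2444 to 2530) in library 2, Rsad2, an antiviral enzyme, at 1246 and 1125 CPM, and Irf7, a transcription factor of the interferon response, at 1351 and 1227 CPM. Monocyte-like cells also led for 7 of the 14 chemokines with 1 leading class, among them Cxcl2, which draws neutrophils, at 3079 and 7023 CPM, Cxcl10, which draws T cells, at 1919.6 and 2267 CPM, and Ccl2, which draws monocytes, at 1115 and 1116 CPM. They led for 6 of 10 genes of the hypoxia and glycolysis list, including Vegfa, an angiogenic factor, at 81.0 and 211 CPM, and Slc2a1, a glucose transporter, at 109 and 141 CPM.

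Macrophage-like cells led for 5 of 7 efferocytosis genes, which serve the uptake of dying cells: Mertk stood at 90.0 and 71.6 CPM, Gas6 at 111 and 125 CPM, and Abca1, a lipid exporter, at 212 and 294 CPM. Migratory DC-like cells led for 4 of 5 costimulation genes, with Cd40 at 139 and 146 CPM, and for 3 of 4 checkpoint ligands, with Cd274, which encodes PD-L1, at 228 and 154 CPM. NK cell-like cells led for 6 of 8 cytotoxic genes, of which Gzma, Gzmc and Prf1 also lead their clusters and so describe them. Klrk1, an activating receptor, stood at 562 and 430.1 CPM, and Gzmb, a granule protease, at 2088 and 3293 CPM. Of 13 reported miR-21 targets with 1 leading class, 5 peaked in regulatory T cell-like cells, including Pdcd4, a translation inhibitor, at 487 and 390 CPM, and Smad7, an inhibitor of TGF-beta signalling, at 713 and 385 CPM. The cDC2-like class led for all 7 MHC class II genes that had 1 leading class. Of these, H2-Aa, H2-Ab1, H2-Eb1, Cd74 and H2-DMb1 also lead that cluster and so describe it, while H2-DMa and Ciita do not.

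Within macrophage-like cells, genes of MHC class II presentation, which display antigen to CD4 T cells, were higher in library 1. All 7 measured members lay on that side and 6 of them were past the 2-fold limit, that is, at least 2-fold apart with an interval that excludes 1.5-fold. H2-Aa stood at 3956 CPM in library 1 and 557 CPM in library 2, a log2 ratio of 2.83 (exact binomial interval 2.79 to 2.86), H2-Eb1 at a ratio of 2.86 (2.81 to 2.90), Cd74, the invariant chain, at 2.43 (2.40 to 2.45), and Ciita, the master regulator of the family, at 3.61 (3.18 to 4.04). The median of the list was 2.77, beyond the central 95% of 10000 random lists matched on expression (−0.38 to 0.39). H2 genes are close relatives of one another, so counts of single members are uncertain. Mgl2, Retnla and 4 of the MHC class II genes also lead cluster 4. More cells of that kind inside the class in library 1 would shift these genes the same way. Cluster 4 itself held more Mgl2 (205 and 29.9 CPM) and Retnla (201 and 31.6 CPM) in library 1. Mgl2 stood at 92.7 CPM in macrophage-like cells of library 1, above cluster 4 of library 2. Cells of cluster 4 at their library 2 level thus do not give the Mgl2 difference by themselves. The cDC2-like class held more Mgl2, at 451 CPM in library 1 and 221 CPM in library 2. Cells of that kind inside the class in library 1 could thus give the difference, and this was not tested.

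Interferon genes lay on the same side in these cells. The interferon gamma list had a median of 1.01 (random range −0.25 to 0.23), with 8 of 15 measured members past the 2-fold limit, among them Iigp1, a GTPase that attacks vacuoles holding pathogens, at 1.64 and Cxcl9, a T cell chemoattractant, at 1.53 (1.44 to 1.62). The type I interferon list had a median of 0.72 (−0.24 to 0.13) with 3 of 20 members past the limit, and MHC class I presentation one of 0.60 (−0.31 to 0.24). With cluster 4 counted among the macrophage-like cells the interferon gamma median was 0.50 and the type I median 0.16, so the size of both depends on where the class ends. The dissociation stress list lay on the same side, with a median of 0.18 (−0.25 to 0.15), and so did Gm42418, a transcript that overlaps ribosomal RNA, at 34661 and 13378 CPM. Both can be signs of handling or RNA quality. The genes with the highest ratios among those named by rank, which need 50 CPM in 1 library, were Mgl2, a galactose-binding lectin, at 4.50 (4.18 to 4.83), and Vcam1, an adhesion molecule, at 3.84 (3.62 to 4.06). Leaving aside the MHC class II genes, the next were Serpina3g at 2.68, Anpep at 2.42, Spon1 at 2.42 and Ddhd1 at 2.23.

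Library 2 was higher in the oxidative stress and metallothionein list, with a median of −0.77 (random range −0.24 to 0.34), and 2 of its 10 members were past the 2-fold limit. The hypoxia and glycolysis list had a median of −0.37 (−0.27 to 0.34) with 2 of 11 members past the limit, but that median turned to 0.048 with cluster 4 counted in and was −0.2645 after free RNA was subtracted, inside a random range that starts at −0.2669, so no direction is read for the list. Slc7a11, a cystine importer, stood at −1.72 (−2.33 to −1.18), Vegfa at −1.60 (−2.08 to −1.15) and Bnip3, a mitophagy receptor, at −1.66 (−2.26 to −1.11). Chemokines had a median of −0.32 (−0.29 to 0.18), which came inside the random range with doublets kept (−0.086), with equal cluster weights (−0.14) and after free RNA was subtracted (−0.22), so no direction is read for the list. Members went both ways: Cxcl2 stood at −1.34 (−1.40 to −1.28) and Ccl8 at 2.17 (2.12 to 2.23). Among genes named by rank, Ctla2a stood at −2.96, Cxcl14 at −2.42, Hilpda, a lipid droplet protein, at −2.32, Clec4d at −2.20, Pf4 at −1.99, Nxpe5 at −1.95 and Spp1, which encodes osteopontin, at −1.88. Free RNA made up an estimated 0.51 of the Ctla2a level in library 1 and 0.48 in library 2, close to the limit of 0.5. Pf4 is among the markers that named this class and leads its clusters 1 and 16, so its ratio may describe the make-up of the class. Gzmc at −3.54, Gzmb at −2.72 and Nkg7 at −2.12 were also named, and the cytotoxic list had a median of −1.99 (−0.40 to 0.26). Free RNA made up an estimated 5.33% of UMIs in library 1 and 15.5% in library 2. That estimate alone gives 5.12, 2.18 and 1.63 times the library 2 level of these 3 genes. It is thus too high for them, and how much of their level is free RNA is not known. After subtraction 5 members of the list kept a level and their median turned to 3.81, so no direction is read for the list. The mast cell list stood at 0.883 and 99.8 CPM in these cells, so markers of another cell type also differ between the libraries inside this class.

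The p53 list had a median of 0.21 in macrophage-like cells (random range −0.20 to 0.24), the reported miR-21 targets 0.15 (−0.29 to 0.25), the NF-kB targets 0.06 (−0.19 to 0.30), efferocytosis 0.08 (−0.29 to 0.35), costimulation 0.23 (−0.36 to 0.47) and the pro-inflammatory list 0.11 (−0.31 to 0.38), all inside the random range. The list of alternatively activated and tumour macrophage genes had a median near 0 with members far apart, from Mgl2 and Retnla, a secreted resistin-like protein, at 4.32 (3.86 to 4.79), to Spp1. This class rested on 113 cells and 2266008 UMIs in library 1 and on 1583 cells and 30568029 UMIs in library 2, mostly from cluster 1 in each.

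**Figure D2:**
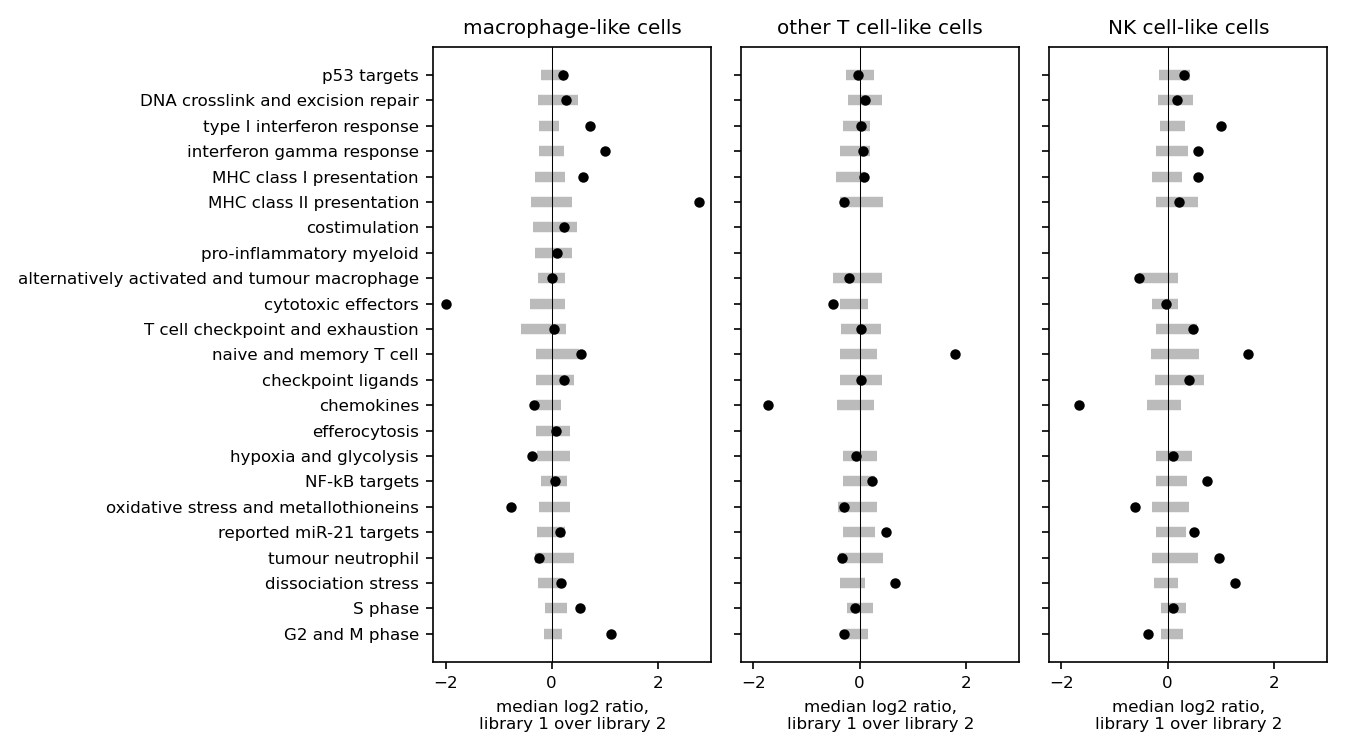
Median log2 ratio of CPM, library 1 over library 2, of each fixed gene list (points) in macrophage-like, other T cell-like and NK cell-like cells, with the central 95% of 10000 random lists of the same size and expression as grey bars. The MHC class II list in macrophage-like cells, at 2.77, lies farthest to the right.

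Within other T cell-like cells, genes of naive and memory T cells were higher in library 1, and some cytotoxic genes were higher in library 2. All 8 members of the naive and memory list were past the 2-fold limit, with a median of 1.80 (random range −0.36 to 0.32). S1pr1, a receptor for exit from tissue, stood at 2.77 (2.503 to 3.03), Ccr7, a lymph node homing receptor, at 2.37 (2.20 to 2.53), Slamf6 at 2.37, and the transcription factor Tcf7 at 1.85 (1.69 to 2.01). The cytotoxic list had a median of −0.49 (−0.37 to 0.16) with 3 of 12 members past the limit toward library 2, with Gzma at −2.95 (−3.24 to −2.68) and Gzmb at −1.82 (−1.88 to −1.77), while Ifng stood at 0.22 (0.08 to 0.36). This list of naive genes also served to set the naive-type clusters apart, so its members are partly fixed by the naming of the classes. S1pr1, Tcf7, Il7r, Dusp10 and Gm12840 are among the genes named for library 1 here. They also lead cluster 3, a naive-type cluster with 1305 cells in library 1 and 1 in library 2. Naive-type cells inside this class in library 1 would thus give the same picture. The free RNA estimate rests on macrophage and B cell markers here and cannot show such cells.

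The dissociation stress list, made up of immediate early and heat shock genes, had a median of 0.67 in these cells (−0.37 to 0.11), with 3 of 16 members past the limit toward library 1 and 1 toward library 2. Gm42418 lay on the same side, at 20904 and 6933 CPM. The reported miR-21 targets had a median of 0.49 (−0.31 to 0.29) with 1 of 13 members past the limit; below it were Smad7 at 0.95 (0.88 to 1.03), Btg2 at 0.71 (0.64 to 0.78) and Pdcd4 at 0.52 (0.43 to 0.60). The immune cells carried no knockout by design, so these targets check no label. The type I interferon list had a median of 0.03, the interferon gamma list 0.06, the checkpoint list 0.03 and the p53 list −0.02, all inside the random range. Other genes named for library 1 were Tsix at 9.23 (7.37 to 12.29, from 303 and 2 UMIs), Il7r at 1.76, Gm12840 at 1.95, Arhgap31 at 1.86, Dusp10 at 1.73 and Hspa1b at 1.69, and for library 2 AA467197 at −1.87, Klra5 at −1.71 and Gzmf at −1.61. The myeloid genes Lyz2 at −3.52, Cxcl2 at −3.06, C1qb at −2.39, Apoe at −2.28 and C1qa at −1.90 were mostly at the level of free RNA. The chemokine list stood at −1.72 (−0.43 to 0.27), and at −0.79 over the 9 of 11 members that kept a level after free RNA was subtracted, so free RNA accounts for part of it. Tsix lies antisense to Xist, and Hspa1b, Klra5 and Gzmf have near-identical relatives, so these values are uncertain.

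Within NK cell-like cells, interferon, NF-kB and stress genes were higher in library 1, and metallothioneins and several granzymes were higher in library 2. The naive and memory T cell list also lay toward library 1. It had the highest median of the class, 1.51 (random range −0.31 to 0.59), with 3 of 5 measured members past the 2-fold limit. The type I interferon list had a median of 1.01 (random range −0.15 to 0.34), with 10 of 19 measured members past the 2-fold limit, such as Cmpk2 at 1.81 (1.35 to 2.25) and Rsad2 at 1.44 (1.21 to 1.67). The NF-kB list had a median of 0.73 (−0.21 to 0.37) with 3 of 12 members past the limit, the interferon gamma list 0.57 (−0.21 to 0.39) with 1 of 13, and MHC class I presentation 0.58 (−0.28 to 0.28) with 1 of 10, so these are mostly small shifts. The dissociation stress list had a median of 1.26 (−0.26 to 0.20), with 10 of 16 members past the limit toward library 1 and 1 toward library 2. The heat shock genes Hspa1b at 3.14 (3.04 to 3.24) and Hspa1a at 2.95 (2.83 to 3.06) lay furthest toward library 1. The dissociation stress list can be a sign of how tissue was handled, and it lay on the same side as the interferon and NF-kB genes. Handling and activation of these cells in the tumour cannot be told apart here.

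The metallothioneins Mt2, at −3.64 (−4.45 to −2.94), and Mt1, at −3.18 (−3.42 to −2.95), which bind metal ions, were the genes furthest toward library 2 that were not at the level of free RNA, and the oxidative stress list holding them had a median of −0.62 (−0.29 to 0.40). The granzymes Gzmd at −2.81 (−2.92 to −2.69), Gzme at −2.29, Gzmg at −1.78 and Gzmc at −1.06 lay on the same side, whereas Gzma stood at −0.10 (−0.14 to −0.06) and Ifng, the gene for interferon gamma, at 1.41 (1.26 to 1.55). The cytotoxic list as a whole had a median of −0.02 (−0.29 to 0.20). Ccl5 at 1.94, Ccl3 at 1.89 and Ccl4 at 1.16, chemokines made by activated NK cells, were higher in library 1. The chemokine list as a whole lay toward library 2, with a median of −1.67 (−0.38 to 0.25) and 5 of 11 members past the limit on that side against 3 toward library 1, but the median was 1.01 over the 8 members that kept a level after free RNA was subtracted. Also higher in library 1 were Cxcr4 at 2.07, Klf2 at 2.04, Cited4 at 1.94 and Il18rap, a subunit of the interleukin 18 receptor, at 1.88. Ifitm1 stood at −1.76. The reported miR-21 targets had a median of 0.50 (−0.22 to 0.34) with 2 of 12 members past the limit, with Spry2 at 1.16 (0.99 to 1.32) and Smad7 at 0.93 (0.80 to 1.06).

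Tsix at 7.02 and Gm42418 at 1.99 were also named for library 1, and Lyz2 at −3.28, C1qa at −2.81, C1qb at −2.35 and Apoe at −1.94 for library 2, the last 4 at or near the level of free RNA. Gzmd, Gzme and Gzmg, and the members of the Hspa1 and Mt pairs, are close paralogs among which counts can be split. Scaling by TMM moved the median gene by 0.21 on the log2 scale in NK cell-like cells, by 0.11 in macrophage-like cells and by 0.10 in other T cell-like cells, and median-of-ratios scaling moved it by 0.13 in NK cell-like cells; no list median outside its random range changed sign under either.

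**Figure D3:**
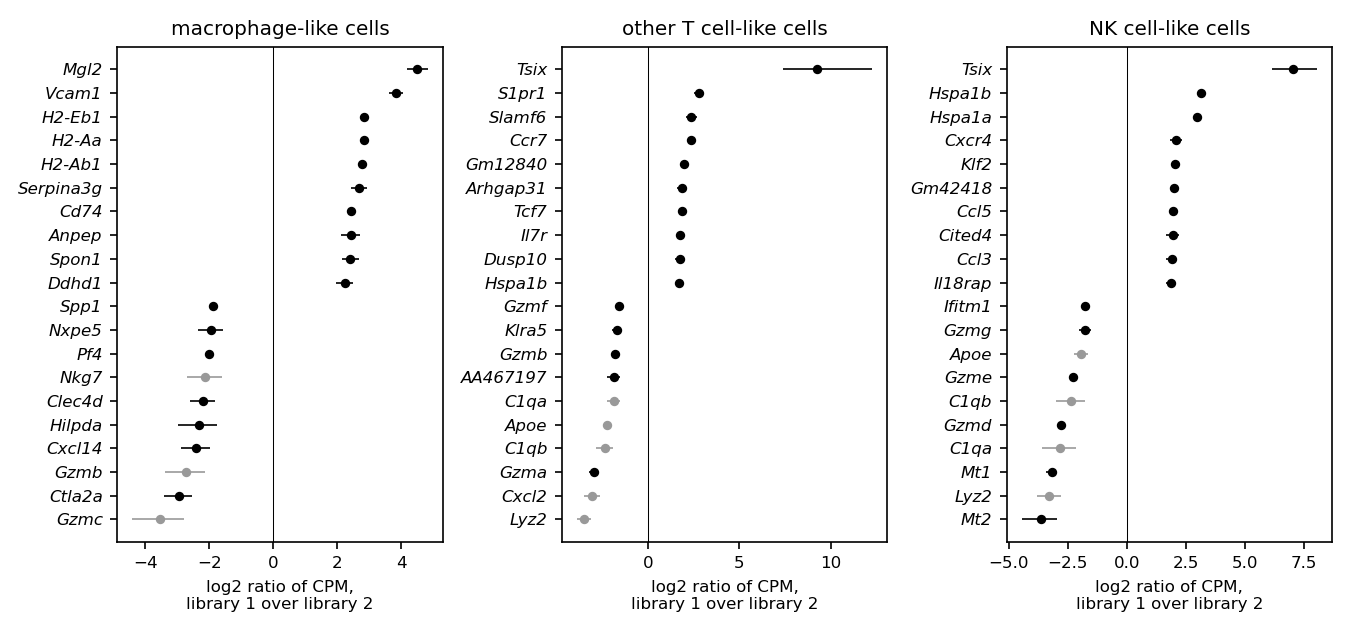
Log2 ratio of CPM, library 1 over library 2, with exact binomial 95% intervals, of the genes named by rank in 3 classes. Grey points are genes whose ratio was not kept after allowing for free RNA, such as Lyz2 in NK cell-like cells at −3.28.

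The share of cells with at least 2 UMIs from the G2 and M phase list, after each cell was thinned to 1000 UMIs, was 42.3% (36.7 to 48.1%) in library 1 and 56.2% (53.3 to 59.1%) in library 2 for other T cell-like cells, 29.4% (22.4 to 37.1%) and 42.6% (39.7 to 45.6%) for NK cell-like cells, and 34.5% (25.8 to 44.0%) and 22.99% (20.9 to 25.1%) for macrophage-like cells. Naive-type T cell-like cells, which rest outside the cell cycle, reached 25.7% (24.0 to 27.4%) in library 1 at a median of 6128 UMIs. Shares below that, such as those of monocyte-like cells (13.9% and 9.22%), are not set apart from background. Neither is the NK cell-like share of library 1, whose interval includes 25.7%. The macrophage-like interval of library 1 starts close to that value. The macrophage-like share of library 2 lies below 25.7%. Yet cluster 16, whose leading genes include Mki67, holds 32 of the 113 and 237 of the 1583 macrophage-like cells, so a cycling part is present in both libraries. Without thinning the shares lay between 85.0 and 98.2% in the 3 compared classes. The higher shares of library 2 went with a different mix of clusters: cluster 8, led by histone genes and Mki67, holds 72 of 300 other T cell-like cells in library 1 and 459 of 1137 in library 2, and cluster 11 holds 21 of 160 and 337 of 1138 NK cell-like cells. The shares were not recomputed with equal cluster weights. Cluster 8 is itself led by genes of cycling cells, so mix and cycling cannot be told apart there. The G2 and M list had a median of −0.30 (−0.25 to 0.15) in other T cell-like and −0.37 (−0.12 to 0.29) in NK cell-like cells, but with equal cluster weights these turned to 0.088 and 0.26, so no direction is read within clusters. Mki67, a proliferation marker, peaked in other T cell-like cells at 255 and 261 CPM, as did 15 of 21 S phase genes but only 5 of 27 G2 and M genes, and Pcna, the replication clamp of S phase, stood there at 222 and 167 CPM. The S phase list had a median of −0.08 (−0.24 to 0.25) in other T cell-like cells. In macrophage-like cells it had one of 0.54 and the G2 and M list 1.13, but both turned with the treatment of doublets and with the class boundary, so no direction is read.

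The targeted locus was checked as far as these data allow. Mir21a lies on chromosome 11 at 86584067 to 86584158 on the minus strand of GRCm38, inside the gene Vmp1 (86583865 to 86683836, same strand), where it overlaps an exon 202 bases from the gene's 3′ end. Mir21a was not analysed here. Vmp1, which encodes a membrane protein of autophagy, stood at 69.9 CPM (67.6 to 72.2) over all cells of library 1 and 112 CPM (110.0 to 114) of library 2. Within classes it stood at 109 and 104 CPM in macrophage-like cells, 63.6 and 59.7 CPM in other T cell-like cells and 68.3 and 55.9 CPM in NK cell-like cells. The knockout was made in the injected cells and not in the leukocytes, so Vmp1 here checks no label and was not used to assign a library.

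Markers of cell types outside the CD45 gate were low except for those of fibroblasts. The epithelial and tumour cell list summed to 34.9 CPM in library 1 and 23.9 CPM in library 2, the endothelial list to 45.9 and 21.2 CPM, the erythroid list to 0.595 and 0.105 CPM and the platelet list to 1.07 and 2.48 CPM. The fibroblast list summed to 1034 and 1369 CPM and stood mostly in the Ptprc-low clusters, at 36735 and 40020.3 CPM in cluster 22. Cluster 15, also low in Ptprc, scored highest for fibroblasts, but at 0.35 with 1 raised marker, under the limits for a name. Clusters 14 and 15 of library 1 also held Y-linked RNA, as given below. The low sums of the epithelial and tumour cell list thus do not show that injected cells were absent.

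Genes that depend on the sex chromosomes, fixed as a check of the libraries, set them apart. In CD45-positive clusters Xist, the RNA that silences 1 of the X chromosomes of female cells, stood at 796 CPM in library 1 and 0.296 CPM in library 2, and 83.9% and 0.178% of cells held a UMI of it. The 4 Y-linked genes of the list together had 13 UMIs, or 0.279 CPM, in the CD45-positive clusters of library 1 and none in library 2, where a count of 0 allows up to 0.0307 CPM.

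**Figure D4:**
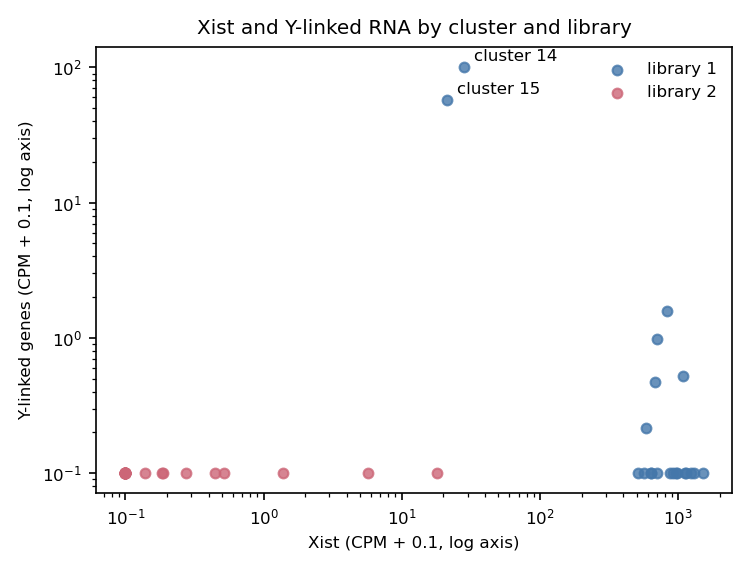
Xist (horizontal axis) and the 4 Y-linked genes together (vertical axis), each as CPM plus 0.1 on a log axis, with 1 point per cluster and library. Clusters 14 and 15 of library 1 stand apart with 100.02 and 57.1 CPM of Y-linked RNA, and all clusters of library 2 are at 0 for the Y-linked genes.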

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

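The 3 tests of the T and B cell pattern and the test of whether Y-linked genes were counted in library 2 were chosen after the result was seen, as was the calculation of the mix with cluster 4; the other tests here were fixed before their values were computed. These 3 values appeared in genes that no comparison uses. Xist reached 795.71 CPM in the CD45-positive clusters of library 1, and Y-linked RNA reached 100.02 CPM in cluster 14 and 57.07 CPM in cluster 15 of the same library, all above what a count of 0 allows. In those clusters, low in Ptprc and led by genes of fibroblasts and contractile cells, 86.3% (73.7 to 94.3%) and 61.5% (40.6 to 79.8%) of cells held a Y-linked UMI, and Xist stood at 28.1 and 21.2 CPM. Cluster 22, also low in Ptprc, held no Y-linked UMI in library 1 and had Xist at 637 CPM. No explanation of the Y-linked RNA in clusters 14 and 15 was tested.

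Library 2 had neither Xist (29 UMIs in 97843777) nor Y-linked RNA (0 UMIs) in its CD45-positive clusters. A male host was the explanation first weighed: it predicts Y-linked RNA, of which none was counted, up to a limit of 0.0307 CPM. Y-linked genes gone uncounted in library 2 was weighed in its place. The only gene annotated on Y with counts there was Gm47283, with 24 UMIs, which lies near the end that Y shares with X, so this stays open. Both libraries stand in 1 matrix with the same genes, and Eif2s3y (168 UMIs) and Ddx3y (162 UMIs) were counted in library 1. A failure to count such genes would thus have to lie in library 2 alone. A lower yield of nuclear RNA is argued against by 6 other nuclear long non-coding RNAs, whose median log2 ratio was 0.30, library 1 over library 2. A single X chromosome in the host of library 2 predicts lower levels of genes that escape X silencing; 5 such genes exceeded other X-linked genes by a median of 0.87 in library 1, from 0.18 for Pbdc1 to 1.26 for Kdm6a, which a male host whose Y-linked RNA went uncounted would also show.

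Naive-type T cell-like and B cell-like cells stood almost wholly in library 1. The higher UMI minimum of library 2 is argued against, since 53.03% of library 1 cells above that minimum were still naive-type. Fewer UMIs per cell in library 2 stays undecided. At the median its other T cell-like cells held 1.07 times as many and NK cell-like cells 1.38 times. The ratio was 0.94 in macrophage-like, 0.93 in regulatory T cell-like and 0.74 in monocyte-like cells. Medians of barcodes already past a UMI limit also cannot show cells lost below it. Lymphoid tissue taken with the tumour of library 1 may have brought these cells, and the naive-type share of T cells there, 82.1%, would look the same had such cells entered the tumour, so these cannot be told apart. The tumour cells' miR-21 status stays open and untested, since the libraries are not mapped to the groups.

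MHC class II genes were higher in macrophage-like cells of library 1. Free RNA from B cells and dendritic cells is argued against, since the median log2 ratio of the list was 2.96 after that level was subtracted. The boundary with cluster 4, led by genes that include MHC class II genes, stays open: counting that cluster in gave a median of 2.38, but cluster 4 is then 332 of 445 cells in library 1 and 649 of 2232 in library 2, so the low ratio predicted for a boundary effect was the wrong bound. That mix alone, with the same level per cluster in both libraries, gives 0.46 with averaged macrophage levels and 1.22 with those of library 2, both below 2.38, but the boundary also sets these shares and levels, so neither decides. Other differences between the animals or their handling, and the tumour cells' miR-21 status, were not tested and stay open.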

How the results depend on the processing

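These 5 settings were chosen after the data were seen: subtraction of free RNA from ratios, cluster 4 counted with the macrophage-like cells, cells of at least 10000 UMIs, named CD45-positive classes only, and the tolerance for list medians. No paired analysis was possible because each group has 1 library and no result comes from a test. Over all settings, 209 values of class shares stayed within their counting interval and 75 moved, 346 ratios of named genes stayed, 87 moved and 1 reversed, and 316 list medians stayed, 72 moved and 10 reversed. Of gene levels, 66 stayed and 60 moved, and of cycling shares 2 stayed and 16 moved. Requiring at least 1000 UMIs, dropping the UMI minimum and dropping the count minimum changed no value that was compared. The cause was not tested for any value below unless the setting's own construction gives it. Depth limits the comparisons through library 1, where the macrophage-like class holds 113 cells and 2266008 UMIs, against 1583 cells and 30568029 UMIs in library 2.

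For class shares, a mitochondrial limit of 5% gave, in library 1, 6.14% B cell-like, 3.77% NK cell-like, 4.42% macrophage-like and 6.91% other T cell-like cells. With doublets kept, macrophage-like cells took 1.32% of library 1 and 18.7% of library 2, naive-type T cell-like cells 52.9% of library 1 and other T cell-like cells 15.96% of library 2. Macrophage-like cells took 8.98% and 33.0% at Leiden resolution 0.5, 0.904% and 15.8% at resolution 2.0, 5.18% of library 1 with 4000 variable genes and 17.2% of library 2 with 15 principal components. Naive-type T cell-like cells took 42.2% of library 1 at resolution 2.0. Cells of at least 10000 UMIs were, in library 1, 1.38% B cell-like, 6.90% NK cell-like, 6.31% macrophage-like, 22.6% naive-type T cell-like and 11.05% other T cell-like, and in library 2, 19.7% NK cell-like, 30.25% macrophage-like, 0.0629% naive-type T cell-like and 14.4% other T cell-like. Among named CD45-positive classes only, a smaller total by construction, library 1 had 10.4% B cell-like, 3.802% NK cell-like, 64.3% naive-type T cell-like and 7.13% other T cell-like cells, and library 2 had 21.6% NK cell-like, 29.99% macrophage-like and 21.5% other T cell-like cells. For these 5 classes the library with the higher share stayed the same, but every total kept the naive-type T cell-like and B cell-like cells. Among cells of at least 10000 UMIs it changed for monocyte-like cells (3.81 and 1.97%), gamma-delta T cell-like cells (0.592 and 0.273%) and pDC-like cells (1.18 and 0.147%), in each case to library 1. Monocyte-like cells took 5.81% of library 1 and 17.6% of library 2 with 15 principal components, 5.53 and 19.05% with 4000 variable genes and 5.003 and 17.8% at resolution 2.0. The gamma-delta T cell-like and cDC1-like classes were not found with 15 principal components or at resolution 0.5.

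For list medians in macrophage-like cells, TMM scaling gave 0.61 for type I interferon, 0.074 for dissociation stress, 0.43 for S phase and 1.015 for G2 and M phase. With doublets kept, the S phase median reversed to −0.67 and the G2 and M median to −0.47; type I interferon stood at 0.98, MHC class II at 1.96, cytotoxic effectors at −1.58, chemokines at −0.086, oxidative stress at −0.52 and dissociation stress at 0.29. With equal cluster weights, the S phase median reversed to −0.15, and type I interferon stood at 0.88, chemokines at −0.14 and G2 and M at 0.16. With cluster 4 counted in, S phase reversed to −0.20, G2 and M to −0.031 and hypoxia and glycolysis to 0.048; type I interferon stood at 0.16, interferon gamma at 0.50, MHC class II at 2.38, cytotoxic effectors at −2.20, naive and memory genes at 1.22 and dissociation stress at 0.36. With free RNA subtracted, naive and memory genes reversed to −0.25, and S phase stood at 0.66 and G2 and M at 1.37.

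In other T cell-like cells, the chemokine median was −1.43 with doublets kept and −0.76 with free RNA subtracted, and the G2 and M median was −0.40 under TMM and reversed to 0.088 with equal cluster weights. In NK cell-like cells, TMM gave 0.80 for type I interferon, 0.36 for interferon gamma, 0.37 for MHC class I, −1.88 for chemokines, 0.53 for NF-kB targets, −0.83 for oxidative stress, 0.29 for reported miR-21 targets, 1.06 for dissociation stress and −0.58 for G2 and M. Median-of-ratios scaling gave 0.875 for type I interferon, 1.13 for dissociation stress and −0.50 for G2 and M. Equal cluster weights gave 0.65 for the tumour neutrophil list, 0.96 for dissociation stress and a reversed 0.26 for G2 and M. With free RNA subtracted, type I interferon stood at 1.18, the chemokine median reversed to 1.00, and the ratio of C1qb reversed to 0.10.

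The cycling shares, in the order library 1 then library 2, depend on their definition by construction. Thinning to 2000 UMIs gave 32.2% of macrophage-like cells in library 2, 64.3 and 74.4% of other T cell-like cells and 55.0 and 58.0% of NK cell-like cells. A limit of 3 UMIs gave 17.3% of macrophage-like cells in library 2, 29.3 and 44.4% of other T cell-like cells and 20.62 and 31.55% of NK cell-like cells. Without thinning the shares were 85.0 and 94.2%, 96.0 and 97.2%, and 97.5 and 98.2%. In macrophage-like cells the order of the libraries reversed without thinning.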

Other observations

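No explanation is tested in this part, and its values were picked for mention after they were seen. Osteopontin, encoded by Spp1, is known as a product of tumour macrophages, yet its level in NK cell-like cells, at 498 CPM (469.97 to 526) in library 1 and 1544 CPM (1527 to 1561) in library 2, was above that in macrophage-like cells, at 349 and 1281 CPM. Cluster 21, with 1 and 78 cells, had more of it (7081 and 3097 CPM), as did cluster 14 of library 1 (1094 CPM). The leading classes below hold among the named CD45-positive classes and cluster 4. Migratory DC-like cells led for Il12b, a subunit of interleukin 12 that also leads their cluster and so describes it, at 159 and 640.5 CPM, and for the NF-kB subunits Rel, at 642 and 660.2 CPM, and Relb, at 382 and 290.5 CPM. Gamma-delta T cell-like cells led for the NF-kB inhibitors Nfkbia, at 1693 and 2533 CPM, and Tnfaip3, at 883 and 583 CPM, and for the checkpoint receptor gene Pdcd1, at 73.9 and 164 CPM. pDC-like cells led for Lag3, another checkpoint receptor gene, at 311 and 190 CPM.

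Monocyte-like cells led for the oxidative stress genes Hmox1, which breaks down heme, at 171 and 592 CPM, and Slc7a11, at 122 and 412 CPM; Slc7a11 is among the genes that lead their cluster and so describes it. Lists of neutrophils at rest were sparse: Mmp8 reached 55.7 and 28.0 CPM and Lcn2 19.4 and 8.87 CPM, both in monocyte-like cells. Of the repair list for crosslinks and excision, which acts on cisplatin damage, 2 of 9 genes had the same leading class in both libraries, Brca1 at 21.97 and 24.3 CPM and Brca2 at 19.9 and 19.8 CPM in other T cell-like cells. The median ratio of that list was 0.28 in macrophage-like, 0.10 in other T cell-like and 0.18 in NK cell-like cells, inside the random range each time.

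The 3 B cell-like cells of library 2 carried the plasma cell list at 70518 CPM, against 615 CPM for the 439 of library 1. Across all barcodes, 4 genes had at least 100 UMIs in library 1 and none in library 2: Ighg1 with 10621, Eif2s3y with 168, Ddx3y with 162 and Krt8 with 158. Cluster 24, with 27 cells in library 2 and 0 in library 1, was led by Ctsk, Acp5 and Mmp9, genes of bone-resorbing osteoclasts. Cluster 17, with 4 and 130 cells, held both T cell and monocyte markers and is left as mixed. Vmp1 reached 197 and 230.4 CPM in cluster 14 and 173 and 181 CPM in cluster 15, both low in Ptprc. The mast cell list summed to 3.78 and 29.4 CPM over all cells.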
